A study of Arabidopsis thaliana with 8 samples.

How the data were processed

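Gene expression was measured with Affymetrix ATH1 arrays in Arabidopsis thaliana, with 1 array per sample and 2 arrays in each of 4 groups: wild type kept warm, wild type in the cold, the sfr3 mutant kept warm and the sfr3 mutant in the cold. Per the labels, the wild type was Col-0 and the sfr3 line was obtained by ethyl methanesulfonate mutagenesis of that line. Plants were grown for 38 days at 20 °C and 70% humidity with 8 h of light and 16 h of darkness per day, after 48 h of seed treatment at 4 °C, and had reached growth stage 1.14, per the labels' protocols. The temperature and the length of the cold exposure are not given in the sources used here. The labels name the whole rosette as the wild-type tissue and the aerial parts as the sfr3 tissue, so that a difference in what was collected cannot be separated from the genotype. RNA was labelled with biotin in 1 cycle, per the labels' protocols.

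The deposited values are intensities: MAS5 signals on a linear scale. MAS5 and GCOS are named, without versions, per the submitters' processing notes; how the array background and mismatch probes were handled is not given in the sources used here. The deposited table held 22810 probe sets, and the 2% trimmed mean of every array was 100, as checked on the values. The 64 control probe sets were left out of the tests, which left 22746. A pseudocount of 2.17, the 10th percentile of all values, was added and log2 was taken. Differences are on the log2(signal + pseudocount) scale, which understates the change of dim genes. The 60% of probe sets with the highest mean signal over the 8 arrays (a mean of at least 26.7) were tested, 13648 in all. The number of arrays limits the precision.

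Probe sets were named through the platform's annotation table and a gene table of the assembly TAIR10.1, which was used for names only. Of the 22746 probe sets, 13513 were paired with 1 gene, 503 with several genes and 8730 with none in this table; of the 13648 tested, these numbers were 7336, 277 and 6035. No gene was named from a probe set with several genes, and a probe set without a gene is described by its signals and, where it is plotted, labelled with its identifier. A gene with several probe sets was represented by the one with the highest mean signal.

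All 8 arrays were fitted in 1 linear model with a mean per group in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation and an intensity trend. The model had 4 residual degrees of freedom and 5.17 prior degrees of freedom, and the median residual SD was 0.299 on the log2 scale. The comparisons were cold against warm in each genotype, sfr3 against wild type at each temperature, the interaction (the cold response of sfr3 minus that of wild type), and sfr3 against wild type averaged over the temperatures. P-values were two-sided and were adjusted by the Benjamini-Hochberg method over the probe sets tested in each comparison, and a probe set was called at an adjusted p below 0.05. Every adjusted p of a gene or probe set given below is from limma. Nothing in the labels says that the replicates came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical. Means ± SD are of the scaled signal over the 2 arrays of a group.

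A gene was taken as not above background in a group when its signal on both arrays was under the 95th percentile of 27 bacterial control probe sets on the same array. The fold is then given as a bound, the mean of the brighter group against this background level or the gene's own signal where that was higher. The named genes were chosen by rule: for each comparison, among probe sets paired with 1 gene, called, and with all arrays of one group above all arrays of the other (for the interaction, called only), the 10 with the largest rise and the 10 with the largest fall. To these were added up to 3 called members of each fixed list by size of change, or, where none was called, up to 2 with the smallest p, and ACC1 and ACC2. The design, the named-gene rule, the gene lists and the other settings were fixed before the data were examined.

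Gene lists were fixed by locus: 23 lists with 434 genes, of which 55 were paired with a probe set and 41 were tested. Lists with at least 3 tested members were tested with camera at a preset correlation between genes of 0.01 and adjusted over the 5 lists of each comparison: cold-regulated (COR) genes, flavonoid and anthocyanin synthesis, starch breakdown with sugars and proline, photosynthesis, and plastid fatty acid synthesis. Camera with a correlation estimated from the residuals and the self-contained test fry were alternatives. Calls adjusted over the list alone used the members of 1 list in 1 comparison.

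The computation was tested on simulated data: noise was resampled from the replicate differences of each group, and 200 of the 13648 probe sets were changed in each of 20 sets, 100 by 2-fold and 100 by 4-fold. For cold against warm, 59.8% of the 4-fold and 4.3% of the 2-fold changes were recovered in wild type with 0% false calls, and 62.4% and 13.6% in sfr3 with 19.7% false calls. For sfr3 against wild type in the warm, 57.6% of the 4-fold and 4.7% of the 2-fold changes were recovered with 0% false calls. In the cold, 62.0% and 11.2% were recovered with 16.9% false calls, a mean of 14.9 per set with 200 changed probe sets. That mean depends on how many probe sets are called, so it is not the number expected among the 17 real calls. With no probe set changed, 2 of 20 sets had a call in that comparison, and the most was 1. For the interaction, 16.2% of the 4-fold and 0.2% of the 2-fold changes were recovered with 0.904% false calls. Averaged over the temperatures, 81.2% of the 4-fold and 36.1% of the 2-fold changes were recovered with 2.45% false calls. A common spread for all groups was therefore too small for the cold sfr3 arrays and too large for the others in these simulations.

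The other settings were no filter and a stricter filter (a mean signal of at least 63.5), pseudocounts of 1 and 10.4, quantile normalization, centring of each array on its median, moderation without a trend or with a robust prior, a fit of only the groups compared, the replicate number as a block, a 2-fold minimum, and leaving out each array in turn. A group left with 1 array is then assumed to vary like the other groups. Tallies of the settings in which a gene was called include the main fit. They count the adjusted p alone, without applying the 2-fold minimum. Array weights estimated from the data, gene list tests and agreement of the cold responses without cold sfr3 replicate 1, simulated sets with no change, and further gene groups were added after the data were seen.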

Results

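Transcript levels were measured in above-ground tissue of Arabidopsis thaliana on 8 arrays, 2 for each combination of genotype (wild type Col-0 or the sfr3 mutant) and temperature (warm or cold). The sfr (sensitive to freezing) mutants were isolated as plants that are damaged by freezing after cold acclimation, the gain in freezing tolerance that follows exposure to low, non-freezing temperature. The sfr3-1 mutation is known to lie in ACC1, which encodes the cytosolic acetyl-CoA carboxylase. ACC1 and its close relative ACC2 have no values here, because the annotation paired neither with a probe set. The comparisons ask how each genotype responded to cold, whether the genotypes differed at each temperature, and whether the response to cold depended on the genotype.

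The median signal was between 36.6 and 39.0 on 7 of the arrays and 52.4 on cold sfr3 replicate 1. On that array the 18 hybridisation control probe sets, bacterial transcripts added to every sample, had a median of 5.75 times their median on the other 7 arrays, with 4.75 to 12.7 for single probe sets, against 0.542 to 1.18 on the other arrays. The background level, the 95th percentile of the 27 control probe sets expected to stay dark, was 35.4 on that array and 6.37 to 11.3 on the others. The actin 3'/5' signal ratio was 1.38 on that array and 2.04 to 4.69 on the others, with 4.69 on warm sfr3 replicate 1. The GAPDH ratio was 1.23 on cold sfr3 replicate 1 and 0.836 to 1.03 on the others. The median absolute log2 difference between replicates was 0.552 for cold sfr3, against 0.179 for cold wild type, 0.214 for warm wild type and 0.231 for warm sfr3. Across probe sets, log2 signals of this array correlated with the other cold arrays at r = 0.804 to 0.818, while the other 3 cold arrays correlated at 0.956 to 0.976 and the 4 warm arrays at 0.958 to 0.978. Genes are not independent replicates, so these correlations have no p-value.

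**Figure D1:**
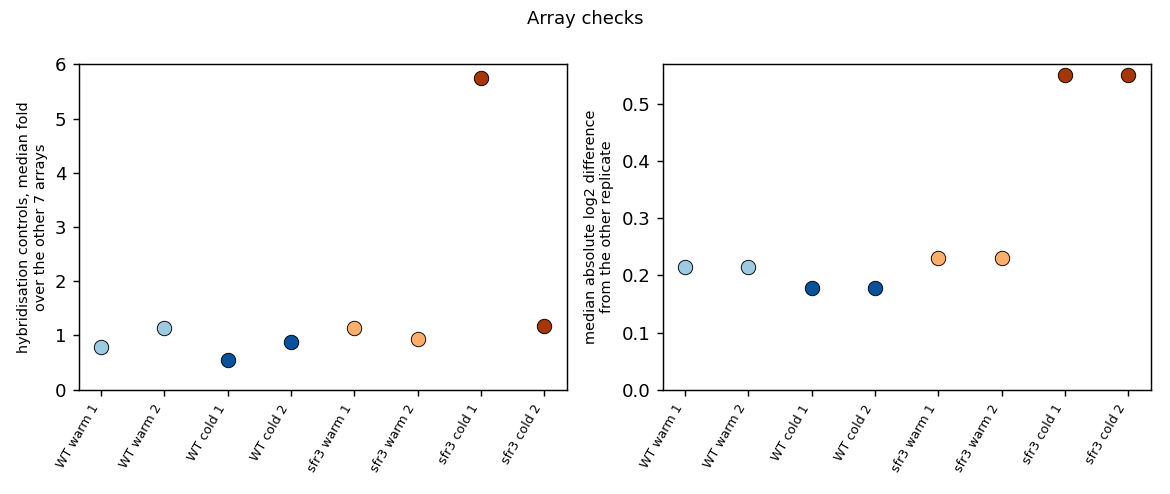
Each point is 1 of the 8 arrays. The left panel gives the median fold of the hybridisation controls over the other 7 arrays, and the right panel gives the median absolute log2 difference from the other replicate of the same group. Cold sfr3 replicate 1 stands at 5.75 on the left, and the cold sfr3 pair stands at 0.552 on the right.

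In wild-type plants the cold raised transcripts of several cold-regulated genes. COR15A and COR15B, whose products protect chloroplast membranes during freezing, rose from 796 ± 328 to 7879 ± 648 (SD, n = 2) and from 517 ± 185 to 3232 ± 591. LTI30, which encodes a dehydrin, rose from 713 ± 50.5 to 5090.4 ± 303, and COR27, which is regulated by cold and light and acts on the circadian clock, from 30.1 ± 6.38 to 335 ± 28.0. PWD, a phosphoglucan water dikinase of starch breakdown, and ATSPS4F, a sucrose phosphate synthase, rose as well. Among the largest falls were GH3.3, which encodes an enzyme that conjugates auxin to amino acids, and AKINBETA1, a regulatory subunit of the SnRK1 kinase complex.

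Of the 7 measured COR genes, 5 rose in wild type, and 5 when adjusted over the list alone. The log2 changes were 3.40 for COR27 (adjusted p = 2.47e-05), 3.37 for COR15A (SE 0.27, adjusted p = 5.61e-05), 2.83 for LTI30 (adjusted p = 1.88e-05), 2.67 for COR15B (adjusted p = 1.48e-04) and 2.29 for AT4G33980 (adjusted p = 0.00258). COR47 (0.39, adjusted p = 0.414) and LEA4-5 (0.39, adjusted p = 0.795) did not pass. The list stood higher than other genes by camera (adjusted p = 3.05e-05; adjusted p = 0.0859 with an estimated correlation). Of the 3 genes of starch breakdown, sugars and proline, 2 rose, and 2 when adjusted over the list alone: PWD from 180.4 ± 22.5 to 1035 ± 30.1 (log2 2.51, adjusted p = 5.61e-05) and ATSPS4F from 62.8 ± 8.48 to 298 ± 23.7 (log2 2.21, adjusted p = 3.82e-04). The sugar transporter gene SWEET11 had a log2 value of 0.33 (adjusted p = 0.305). No proline gene of this list was tested. The list had an adjusted p of 0.00765, and adjusted p = 0.101 with an estimated correlation. Of 3 flavonoid genes, 1 rose, and 1 when adjusted over the list alone: UGT78D2, a flavonoid glucosyltransferase, rose from 58.6 ± 3.32 to 185 ± 26.2 (log2 1.61, adjusted p = 7.56e-04). UF3GT had a log2 value of 1.09 (adjusted p = 0.123) and DFR of 0.82 (adjusted p = 0.150). That list had an adjusted p of 0.0455, adjusted p = 0.149 with an estimated correlation, and adjusted p = 0.0675 without cold sfr3 replicate 1.

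None of the 4 photosynthesis genes was called in wild type in the cold (0 over all genes and 0 adjusted over the list alone, median log2 -0.38, list adjusted p = 0.348). They were RCA, LHCB4.1, LHCB4.2 and LHCB4.3, of 27 genes on the fixed list, and do not stand for photosynthesis genes in general. Of the 4 genes of plastid fatty acid synthesis, FATB, an acyl-ACP thioesterase, fell from 519.8 ± 20.2 to 277 ± 13.8 (log2 -0.90, adjusted p = 0.00410), and 3 passed when adjusted over the list alone. The 4 did not pass as a list by camera (adjusted p = 0.680), while fry gave an adjusted p of 0.0260. Their log2 values went both ways, with quartiles of -0.60 and 0.40. The call of FATB was lost without cold wild-type replicate 2 (adjusted p = 0.0577).

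The largest rises in wild type included AT5G03350, a legume lectin family gene, from 112 ± 33.5 to 2242 ± 377 (log2 4.31, SE 0.30, adjusted p = 2.47e-05). AT1G31690, a copper amine oxidase gene, rose from 18.9 ± 8.84 to 518 ± 13.0 (log2 4.70, SE 0.49, adjusted p = 2.17e-04). AT1G06000, a glycosyltransferase gene, was not above background in the warm and was at least 15.2-fold higher in the cold, at 129 ± 1.67 (adjusted p = 3.76e-04). AT1G71000, a DnaJ-domain gene, and AT2G16890, a glycosyltransferase gene, were at least 8.99-fold (adjusted p = 0.00358) and at least 9.56-fold (adjusted p = 0.00404) higher. AT1G17665 was at least 5.87-fold higher (adjusted p = 0.0153). AT1G07050, AT1G19960, AT3G03770 and AT1G48100 rose by log2 4.23, 4.19, 3.92 and 3.85. Among the falls, AT2G20670 dropped from 1289 ± 295 to 13.6 ± 7.72 (log2 -6.43, SE 0.71, adjusted p = 2.82e-04). AT5G19120, an aspartyl protease family gene, fell from 1229.9 ± 151 to 13.7 ± 3.19 (log2 -6.29, SE 0.41, adjusted p = 1.96e-05), and AT2G05540, which encodes a glycine-rich protein, from 2419 ± 49.8 to 61.6 ± 4.34 (log2 -5.25, SE 0.16, adjusted p = 1.31e-06). GH3.3 fell from 302 ± 117 to 9.25 ± 8.55 (log2 -4.92) and AKINBETA1 from 1195 ± 131 to 50.5 ± 0.213 (log2 -4.50). AT4G27450, AT2G32150, AT3G15630, AT1G22890 and AT2G30600 fell with log2 values of -5.03, -4.96, -4.72, -4.59 and -4.53. Without cold wild-type replicate 1 or 2 the calls of AT1G71000 (adjusted p = 0.0958 and 0.0782) and AT2G16890 (0.0749 and 0.0614) were lost. AT1G17665 lost its call without any 1 of the 4 wild-type arrays (adjusted p = 0.0503 to 0.193).

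From lists with fewer than 3 measured members, GI, a clock gene, rose in wild type from 307 ± 75.4 to 828 ± 43.5 (log2 1.45, adjusted p = 9.82e-04). SHN3, a transcription factor of cutin synthesis, and AT5G33370, a cutin synthase gene, rose by log2 2.07 (adjusted p = 0.0430) and 1.05 (adjusted p = 0.0483). STZ, a zinc finger repressor (log2 -2.35, adjusted p = 2.43e-04), the expansin gene EXPA8 (-2.38, adjusted p = 8.70e-04), the senescence regulator WRKY53 (-2.48, adjusted p = 0.0124) and the defensin gene PDF1.2 (-3.51, adjusted p = 0.0127) fell. PYK10, a beta-glucosidase gene used as a root marker, fell from 164 ± 45.1 to 30.3 ± 2.08 (log2 -2.33, adjusted p = 0.00342). The calls of SHN3 (adjusted p up to 0.286), AT5G33370 (up to 0.259), WRKY53 (up to 0.106) and PDF1.2 (up to 0.0868) were each lost without any 1 of the 4 wild-type arrays, and that of SHN3 also without warm sfr3 replicate 1 (0.0515). Of 20 settings, SHN3 and AT5G33370 were each called in 12.

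In all, limma called 3594 of 13648 probe sets (26.3%) for cold in wild type, 1780 higher and 1814 lower, of which 2503 changed at least 2-fold and 1756 were paired with 1 gene. Without wild-type warm replicate 1 or 2 or cold replicate 1 or 2 the count was 1646, 1917, 1754 or 1500, and without cold sfr3 replicate 1 or 2, which contribute only to the common spread, it was 6206 or 6192.

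**Figure D2:**
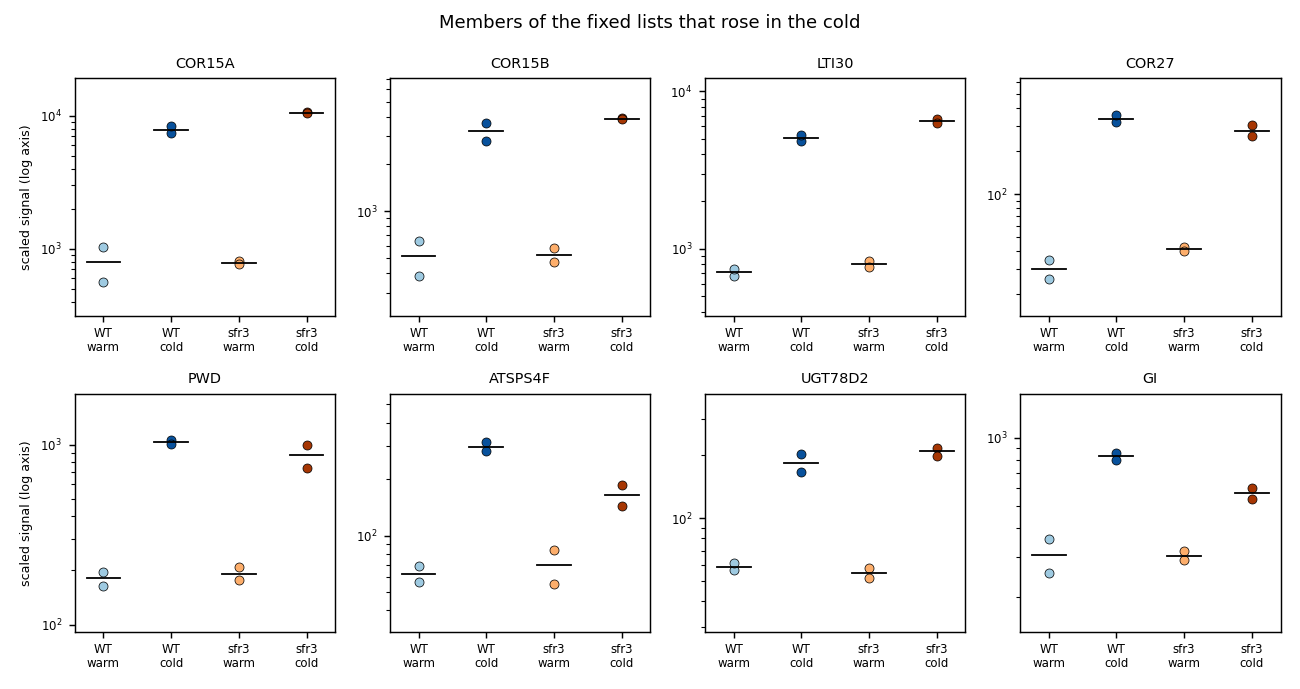
Scaled signal on a log axis of COR15A, COR15B, LTI30, COR27, PWD, ATSPS4F, UGT78D2 and GI in the 4 groups; points are arrays and black bars are means of 2 arrays. In wild type COR15A rose from a mean of 796 to 7879, and in sfr3 from 784 to 10554.

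In sfr3 plants the cold raised 4 of the 7 COR genes: COR15A rose from 784 ± 25.2 to 10554 ± 69.5 (SD, n = 2), LTI30 from 804 ± 49.5 to 6502 ± 300.4, COR15B from 528 ± 74.3 to 3883 ± 27.2 and COR27 from 41.5 ± 2.06 to 277 ± 35.3. PWD, ATSPS4F and SWEET11 of the starch and sugar list rose. HAT2, a homeodomain-leucine zipper transcription factor gene, fell from 501 ± 71.3 to a level not above background, and the auxin response repressor gene IAA29 and the autophagy gene ATG8E were also among the largest falls. Of the cold sfr3 arrays, replicate 1 had the high hybridisation controls given above (5.75-fold).

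Of the 7 COR genes, 4 rose in sfr3, and 4 when adjusted over the list alone. The log2 changes were 3.75 for COR15A (adjusted p = 3.31e-05), 3.01 for LTI30 (adjusted p = 1.42e-05), 2.88 for COR15B (adjusted p = 9.97e-05) and 2.67 for COR27 (adjusted p = 7.61e-05). AT4G33980 had a log2 value of 0.95 (adjusted p = 0.0900), COR47 -0.02 and LEA4-5 -0.91. Without cold sfr3 replicate 1 these 3 had 0.70, 0.45 and 0.48, not called. The list had an adjusted p of 0.00226, and adjusted p = 0.121 with an estimated correlation. All 3 genes of starch breakdown, sugars and proline rose, and 3 when adjusted over the list alone: PWD by log2 2.16 (adjusted p = 1.18e-04), ATSPS4F by 1.24 (adjusted p = 0.00694) and SWEET11 by 0.78 (adjusted p = 0.0229). The list had an adjusted p of 0.0137, and adjusted p = 0.121 with an estimated correlation. Of the 3 flavonoid genes, UGT78D2 (log2 1.90, adjusted p = 3.18e-04) and UF3GT (1.61, adjusted p = 0.0300) rose, and 2 did when adjusted over the list alone. The flavonoid list did not pass by camera (adjusted p = 0.0766), while fry gave an adjusted p of 9.74e-04. Of the photosynthesis genes, 1 of 4 fell, and 1 when adjusted over the list alone: LHCB4.2, a light-harvesting protein gene (log2 -0.91, adjusted p = 0.0384; list adjusted p = 0.708). In plastid fatty acid synthesis FATB fell (log2 -1.04, adjusted p = 0.00200) and AT2G22230 rose (0.77, adjusted p = 0.0400), and all 4 genes passed when adjusted over the list alone. The list did not pass by camera (adjusted p = 0.708), while fry gave an adjusted p of 0.0248. Its median of -0.07 turned to 0.02 under quantile normalization. Calls were lost without warm sfr3 replicate 1 for ATSPS4F (adjusted p = 0.0638), SWEET11 (0.0577), UF3GT (0.123), LHCB4.2 (0.144) and AT2G22230 (0.247). They were lost without warm sfr3 replicate 2 for SWEET11 (0.142), UF3GT (0.108) and LHCB4.2 (0.155). Leaving out cold wild-type replicate 1 or 2 ended the calls of SWEET11 (0.0504 and 0.0503), UF3GT (0.0663 and 0.0718), LHCB4.2 (0.0763 and 0.0763) and AT2G22230 (0.0768 and 0.0770). Leaving out warm wild-type replicate 1 or 2 ended those of LHCB4.2 (0.0644 and 0.0639) and AT2G22230 (0.0668 and 0.0669). Leaving out cold sfr3 replicate 1 ended that of LHCB4.2 (0.0757), and cold sfr3 replicate 2 that of AT2G22230 (0.0668). By adjusted p alone, LHCB4.2 was called in 9 of 21 settings, AT2G22230 in 11 of 21, SWEET11 in 13 of 21, UF3GT in 14 of 20 and ATSPS4F in 18 of 21. LHCB4.2, AT2G22230 and SWEET11 changed less than 2-fold, so the 2-fold minimum ended their calls too, which these tallies leave out.

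The largest rises in sfr3 included AT5G03350 from 92.0 ± 0.132 to 2637 ± 1031 (log2 4.75, SE 0.30, adjusted p = 1.60e-05) and AT3G22240 from 269 ± 30.3 to 6073 ± 210.1 (log2 4.49, SE 0.28, adjusted p = 1.50e-05). AT4G12490, a lipid transfer protein family gene, rose from 79.5 ± 28.2 to 1646 ± 559 (log2 4.34, SE 0.29, adjusted p = 2.19e-05) and AT2G04570, a GDSL lipase family gene, from 29.8 ± 5.88 to 531 ± 56.9 (log2 4.07, SE 0.30, adjusted p = 3.49e-05). AT3G52740, AT1G07050, AT1G71000, AT2G23910, AT1G76960 and AT1G17665 were not above background in the warm and were at least 14.7-, 13.0-, 8.32-, 7.48-, 7.37- and 6.89-fold higher in the cold (adjusted p = 7.98e-04, 1.35e-04, 0.00296, 0.00846, 0.00866 and 0.00722). HAT2 fell at least 27.4-fold, to 6.23 ± 0.109 (adjusted p = 3.02e-06). AT5G19120 fell from 1306 ± 92.0 to 12.5 ± 9.71 (log2 -6.66, SE 0.41, adjusted p = 1.44e-05), ATG8E from 717 ± 221 to 23.8 ± 20.2 (log2 -5.01, SE 0.49, adjusted p = 1.46e-04) and IAA29 from 354 ± 6.41 to 11.8 ± 2.17 (log2 -4.68, SE 0.28, adjusted p = 1.44e-05). AT2G20670, the glutaredoxin gene AT3G62950, AT1G62480 and AT1G62510 fell with log2 values of -6.27, -5.42, -4.84 and -4.73, and AT2G24550 and AT4G32030 fell at least 20.7- and 9.92-fold. Without cold sfr3 replicate 1 the values were -7.62 for AT2G20670 and -4.12 for ATG8E. The call of AT1G76960 was lost without warm sfr3 replicate 2 (adjusted p = 0.0503).

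From the lists with fewer measured members, GI (log2 0.90, adjusted p = 0.00970), the mitotic kinase gene AUR1 (1.07, adjusted p = 0.0229) and AT5G33370 (1.61, adjusted p = 0.00738) rose in sfr3, and SHN3 rose at least 4.21-fold (adjusted p = 0.0142). STZ (-1.33, adjusted p = 0.00443), EXPA8 (-3.13, adjusted p = 2.00e-04), WRKY53 (-2.12, adjusted p = 0.0225; -1.04 without cold sfr3 replicate 1) and PYK10 (201 ± 1.95 to 76.0 ± 50.9, log2 -1.55, adjusted p = 0.0218; -2.27 without cold sfr3 replicate 1) fell. PDF1.2 had a log2 value of -1.97 (adjusted p = 0.0969; 0.00402 without warm sfr3 replicate 2 and 0.0155 without cold sfr3 replicate 2). WSD1, a wax ester synthase gene, had 2.09 (adjusted p = 0.144; 0.0273 without cold sfr3 replicate 1). Without warm sfr3 replicate 1 the calls of GI (adjusted p = 0.0735), AT5G33370 (0.0615), AUR1 (0.144), WRKY53 (0.131) and PYK10 (0.113) were lost, and without warm sfr3 replicate 2 those of AUR1 (0.0585), WRKY53 (0.0898), PYK10 (0.103) and SHN3 (0.0695). Without cold wild-type replicate 1 or 2 the calls of AUR1 (0.0524 and 0.0524) and SHN3 (0.0527 and 0.0555) were lost. AUR1 was called in 15 of 21 settings and SHN3 in 15 of 20.

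In all, 4261 probe sets (31.2%) were called for cold in sfr3 by limma, 2028 higher and 2233 lower. Of these, 3047 changed at least 2-fold and 2145 were paired with 1 gene. The larger count than the 3594 in wild type does not show a broader response, as the common spread was too small for cold sfr3 in the simulations. A fit of only the groups compared reversed the order, with 1867 in sfr3 and 6551 in wild type. Centring each array on its median moved the median of all probe sets by -0.24 and the split from 47.6% higher to 30.9% (1044 higher and 2331 lower). The count was 2027 or 2180 without warm sfr3 replicate 1 or 2 and 7981 without cold sfr3 replicate 2.

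The cold responses of the genotypes were alike in direction for most called probe sets. COR15A, COR15B, LTI30, COR27, PWD and ATSPS4F rose in both genotypes, and AT5G19120 and AT2G20670 fell in both. Of the 3594 probe sets called in wild type, 98.8% changed in the same direction in sfr3, and of the 4261 called in sfr3, 96.8% did in wild type. Both comparisons called 1243 probe sets as higher, where independent lists of these sizes would share 264.5, and 1422 as lower, where they would share 296.8, and 5 were called in opposite directions. The log2 changes correlated across probe sets (Pearson r = 0.801, Spearman rho = 0.736); genes are not independent replicates, and the 2 comparisons share no arrays. Without cold sfr3 replicate 1 the number called in the same direction was 4227 instead of 2665.

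**Figure D3:**
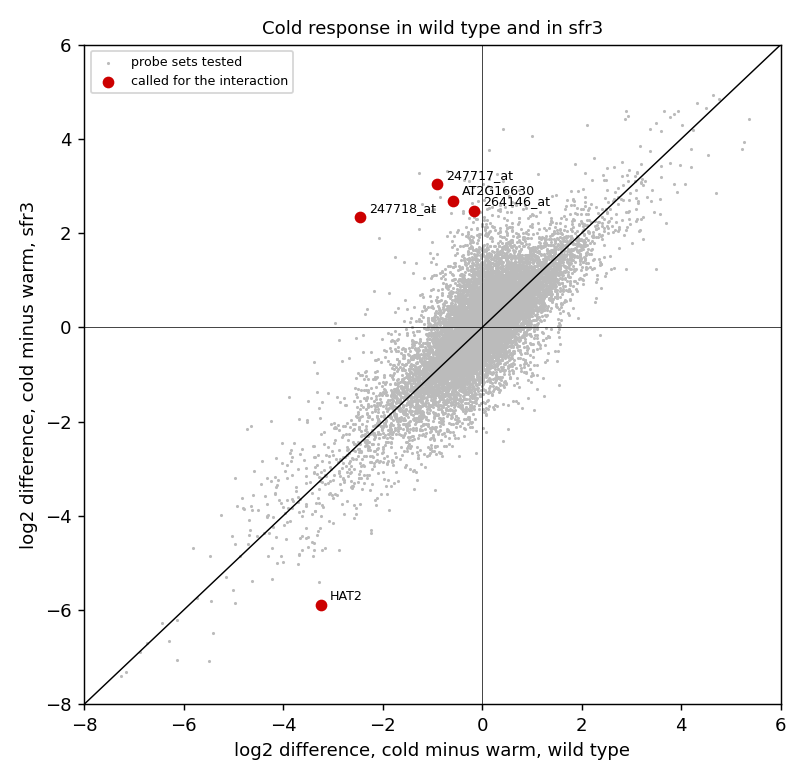
Log2 change of 13648 probe sets (points) from warm to cold in wild type (horizontal axis) and in sfr3 (vertical axis); the diagonal marks equal changes. The 5 probe sets called for the interaction of genotype and cold are red and labelled with the gene or, where no gene is paired, the probe set identifier, and r across probe sets is 0.801.

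In the warm, no gene was called between sfr3 and wild type. COR15A stood at 784 ± 25.2 in sfr3 and 796 ± 328 in wild type (SD, n = 2), LTI30 at 804 ± 49.5 and 713 ± 50.5 and HAT2 at 501 ± 71.3 and 457 ± 40.7. PDF1.2 stood at 226 ± 258 in sfr3 and 711 ± 32.4 in wild type (log2 -2.38, adjusted p = 1), and did not pass the test. By limma, 0 of 13648 probe sets were called, 102 had an unadjusted p below 0.05 where 682.4 would by chance, and the smallest adjusted p was 0.825. In the simulations the common spread was too large for the warm arrays. This comparison recovered 57.6% of the 4-fold and 4.7% of the 2-fold changes there. With only the warm groups fitted, 83.95% of the 4-fold changes were recovered. The lack of calls therefore does not show that the genotypes were alike in the warm.

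The COR list stood slightly higher in warm sfr3 by camera (median log2 0.17, adjusted p = 0.0498; adjusted p = 0.445 with an estimated correlation, and 0.0819 without cold sfr3 replicate 1), with 0 of 7 members called over all probe sets and 0 adjusted over the list alone. Fry, which asks whether the list's own genes move together, gave an adjusted p of 0.893. The other 4 lists did not pass (adjusted p = 0.830), with 0 members called over all probe sets or adjusted over the list alone. Under the alternative settings of limma the count was 0 or 1. A probe set paired with no gene, chosen after its values were seen, stood at 114 ± 9.43 in warm sfr3 and 405 ± 13.3 in warm wild type (log2 -1.81). It was the 1 called when only the groups compared were fitted (adjusted p = 0.00291), with array weights (2.04e-04), and without cold sfr3 replicate 1 (4.26e-04) or 2 (4.88e-04). Without warm sfr3 replicate 2 the 1 call was of another probe set without a gene (log2 -3.75, adjusted p = 0.0423).

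In the cold, AT2G16630, which encodes a proline-rich cell wall protein of the guard cell cuticular ledge, stood at 523 ± 68.6 in sfr3 and 52.0 ± 7.27 in wild type (SD, n = 2). AT5G47330, an alpha/beta hydrolase family gene, stood at 257 ± 1.76 in sfr3 and 14.7 ± 2.72 in wild type, and AT2G04570, the GDSL lipase family gene, at 531 ± 56.9 and 71.9 ± 7.41. AT5G53710 (167 ± 0.242 and 18.8 ± 5.67) and AT2G05540, the glycine-rich protein gene (145 ± 10.6 and 61.6 ± 4.34), were also higher in sfr3. HAT2 was at least 2.53-fold lower in sfr3, where it was not above background, than in wild type, at 46.2 ± 6.27.

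The log2 differences were 3.95 for AT5G47330 (SE 0.34, adjusted p = 0.00177), 3.28 for AT2G16630 (SE 0.21, adjusted p = 5.31e-04), 3.04 for AT5G53710 (SE 0.37, adjusted p = 0.0175), 2.85 for AT2G04570 (SE 0.30, adjusted p = 0.00738) and 1.21 for AT2G05540 (SE 0.16, adjusted p = 0.0296). HAT2, at least 2.53-fold lower, had an adjusted p of 0.00246. AT2G16630 was called in every setting that was run (adjusted p up to 0.0454). Leaving out cold wild-type replicate 1 ended the calls of HAT2 (adjusted p = 0.0644), AT2G04570 (0.145), AT5G53710 (0.110) and AT2G05540 (0.496), and leaving out cold wild-type replicate 2 those of AT2G04570 (0.110), AT5G53710 (0.248) and AT2G05540 (0.348). Leaving out warm wild-type replicate 1 or 2 or warm sfr3 replicate 1 or 2 ended the calls of AT5G53710 (0.0670, 0.0571, 0.0746 and 0.0707) and AT2G05540 (0.146, 0.147, 0.122 and 0.124). With only the groups compared, AT5G47330 had an adjusted p of 0.0576, AT5G53710 0.251, and HAT2 and AT2G05540 0.7095. AT2G05540 was called in only 10 of 21 settings, AT5G53710 in 12 of 20, AT2G04570 and HAT2 in 19 of 21 and AT5G47330 in 20 of 21.

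Limma called 17 probe sets between the genotypes in the cold, 14 higher and 3 lower in sfr3. All had fitted values of at least 2-fold, and 6 were paired with 1 gene. The split was 54 higher and 52 lower without cold sfr3 replicate 1. In simulated sets with 200 changed probe sets 16.9% of the calls in this comparison were false, and sets with none changed had 1 call at most. False calls among the 17 are therefore not excluded. Of those without a gene, 1 stood at 2796 ± 578 in sfr3 and 204 ± 40.8 in wild type (log2 3.76, adjusted p = 4.92e-04) and 1 at 2142 ± 533 and 69.5 ± 25.5 (log2 4.93, adjusted p = 0.00109). The probe set without a gene that differed in the warm under some settings stood at 66.9 ± 26.9 in sfr3 and 403 ± 6.12 in wild type (log2 -2.61, adjusted p = 0.00504), and its call was lost without cold wild-type replicate 1 or 2 (adjusted p = 0.10 and 0.110), under quantile normalization (0.0565) and with only the groups compared (0.251). These 3 were chosen after their values were seen. Of the 17 probe sets, 10 fell and 1 rose from warm to cold in wild type, and 11 rose and 5 fell in sfr3. At an unadjusted p below 0.05 there were 1775. The count was 6 or 7 without cold wild-type replicate 1 or 2, 11 without warm wild-type replicate 1 and 11 without replicate 2, 106 without cold sfr3 replicate 1 and 5372 without cold sfr3 replicate 2. Centring each array on its median moved the median of all probe sets by -0.25 and ended 4 calls. AT2G05540 went from 1.21 (SE 0.16) to 0.96 (SE 0.23, adjusted p = 0.377). The other 3, without a gene, went from 1.498 (SE 0.18) to 1.25 (SE 0.27, adjusted p = 0.377), from 2.56 (SE 0.34) to 2.31 (SE 0.33, adjusted p = 0.0714) and from 2.18 (SE 0.29) to 1.92 (SE 0.29, adjusted p = 0.107).

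None of the 5 gene lists differed between the genotypes in the cold (adjusted p = 0.919 for each), with 0 members called over all probe sets. Adjusted over the list alone, 1 gene of starch breakdown, sugars and proline passed, ATSPS4F at 165 ± 30.1 in sfr3 and 298 ± 23.7 in wild type (log2 -0.85, adjusted p over all probe sets = 0.339), and 0 of the other lists. WSD1 stood at 81.6 ± 59.1 in sfr3 and 5.32 ± 5.43 in wild type (log2 3.50, SE 1.02, adjusted p = 0.333).

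**Figure D4:**
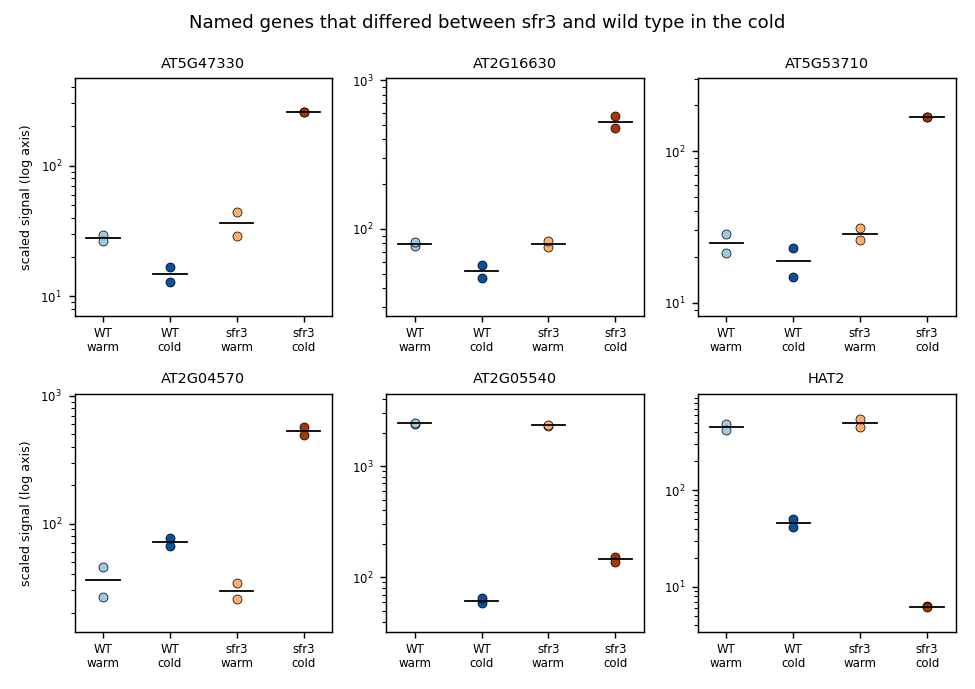
Scaled signal on a log axis of AT5G47330, AT2G16630, AT5G53710, AT2G04570, AT2G05540 and HAT2 in the 4 groups; points are arrays and black bars are means of 2 arrays. In the cold, AT2G16630 stood at a mean of 523 in sfr3 and 52.0 in wild type, and HAT2 at 46.2 in wild type and not above background in sfr3.

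The response to cold itself differed between the genotypes for AT2G16630, a call held in 12 of 20 settings, and less stably for HAT2, called in 8 of 20. AT2G16630 stood at 78.8 ± 3.25 in warm and 52.0 ± 7.27 in cold wild type, and at 79.3 ± 5.03 in warm and 523 ± 68.6 in cold sfr3 (SD, n = 2). HAT2 fell in both genotypes, from 457 ± 40.7 to 46.2 ± 6.27 in wild type and from 501 ± 71.3 to a level not above background in sfr3. A further 3 probe sets, paired with no gene and described here after their values were seen, stood at 2796 ± 578, 2142 ± 533 and 675 ± 139 in cold sfr3 and at 204 ± 40.8, 69.5 ± 25.5 and 92.6 ± 11.2 in cold wild type.

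These were the 5 probe sets called by limma for the interaction, 4 higher and 1 lower, and 803 had an unadjusted p below 0.05, where 682.4 would by chance. The cold response of sfr3 minus that of wild type was log2 3.27 for AT2G16630 (SE 0.30, adjusted p = 0.0111). HAT2 fell at least 2.76-fold more in sfr3 than in wild type (adjusted p = 0.0416). The difference was log2 3.95 (SE 0.32, adjusted p = 0.00682), 4.80 (SE 0.54, adjusted p = 0.0310) and 2.64 (SE 0.30, adjusted p = 0.0310) for the 3 probe sets without a gene, in the same order. Without any 1 of the 6 arrays other than the cold sfr3 pair, the calls of AT2G16630 (adjusted p = 0.0838 to 0.194), HAT2 (0.232 to 0.445) and the last 2 of these 3 probe sets (0.0838 to 0.298 and 0.177 to 0.410) were lost. The call of the first was lost without warm sfr3 replicate 1 (0.144), warm wild-type replicate 1 or 2 (0.0780 and 0.135) or cold wild-type replicate 2 (0.0899). The count was 2 without warm sfr3 replicate 2, 1 without cold wild-type replicate 1 and 0 without any 1 of the other 4 of these arrays, and it was 16 without cold sfr3 replicate 1 and 3802 without replicate 2. It was 3, all higher, under quantile normalization and 0 with each array centred on its median, which moved the median of all probe sets by -0.31, or without the intensity trend. The call of HAT2 was also lost without a filter (adjusted p = 0.0557), with the larger pseudocount (0.106), under quantile normalization (0.154), with centring (0.105) and without the trend (0.153). None of the 5 lists differed in response (adjusted p = 0.731 to 0.987), with 0 members called over all probe sets and 0 adjusted over the list alone.

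Averaged over the temperatures, AT2G16630 (log2 1.64, adjusted p = 0.00714) and AT5G47330 (log2 2.14, adjusted p = 0.0142) were higher in sfr3. Their differences were 0.0075 and 0.34 in the warm and 3.28 and 3.95 in the cold, so the averages come mostly from the cold. The 2 genes were among 7 probe sets called by limma, 6 higher and 1 lower, and all 7 were also called between the genotypes in the cold. The rule for named genes took none of them, because in no case did all 4 sfr3 arrays stand apart from all 4 wild-type arrays for a probe set paired with 1 gene, so both genes are named here after their values were seen. The lower probe set (log2 -2.21, adjusted p = 0.00714) was the one that stood at 66.9 ± 26.9 in cold sfr3. In this comparison 718 probe sets had an unadjusted p below 0.05, where 682.4 would by chance. The count was 22 without cold sfr3 replicate 1, 3251 without cold sfr3 replicate 2 and 0 without any 1 of the other 6 arrays, and also 0 with each array centred on its median or without the intensity trend. None of the 5 lists differed (adjusted p = 0.726 to 0.857), with 0 members called over all probe sets and 0 adjusted over the list alone.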

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

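The tests of the hybridisation controls, the actin and GAPDH ratios, the nearness to the cold mean, the calls without cold sfr3 replicate 1, the size of the differences in the warm, and the single warm sfr3 array were chosen only after the results were seen, as were the plastid-encoded genes as a group.

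Cold sfr3 replicate 1 stood apart in data that no comparison used: its hybridisation controls had a median of 5.75 times that on the other 7 arrays, and the log2 signals of the cold sfr3 pair differed by a median of 0.552. A warm sample under a cold label is argued against, because 79.7% of the probe sets called for cold in wild type lay nearer to the cold than to the warm wild-type mean on this array. The high controls are what less labelled plant RNA on this array, followed by scaling to the common mean, would give, and this may be the source of the spread. Degraded RNA cannot be told apart from it, because the actin 3'/5' ratio of this array, 1.38, was the lowest of the 8 and its GAPDH ratio, 1.23, the highest. A biological difference between the plants of the pair was not tested.

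The cold response differed, by a test of the difference itself, for AT2G16630 (3.27), 3 probe sets without a gene (3.95, 4.80 and 2.64) and, less stably, HAT2 (-2.65, a fitted value from signals not above background in cold sfr3), all 5 among the 17 that differed in the cold. Without cold sfr3 replicate 1 all 17 kept their sign, so none rests on that array alone. AT2G16630 then had 3.41, from 3.28, and AT2G05540 1.14, from 1.21. That fit leaves 1 cold sfr3 array, assumed to vary like the other groups. It cannot tell whether the calls outlast the spread of the pair, so noise stays open. Scaling is argued against for most, because 15 were still called under quantile normalization and 13 with arrays centred on their medians. Centring ended the calls of AT2G05540 (0.96, SE 0.228, from 1.21, SE 0.163) and 3 others, which became smaller but kept their sign, at 1.25, 2.31 and 1.92. Scaling is argued against as the whole of these differences and stays open for part of their size. Under centring none of the 5 interaction calls passed. AT2G16630 went from 3.27 (SE 0.303) to 2.96 (SE 0.399), and the 3 probe sets to 3.63, 4.49 and 2.33 (SE 0.458, 0.544 and 0.430), smaller values with larger errors. HAT2 went to -2.96 as its SE grew from 0.321 to 0.358. Centring moved the median of all probe sets by only -0.31, and all 5 kept their sign and most of their size. This argues against scaling as the whole of the differences in response. Whether they pass the test still depends on the scaling. A sequence difference under the probes would show at both temperatures. It is argued against for the 14 higher in sfr3, of which 0 were higher in the warm by at least 50% of the size. Of the 3 lower, it is argued against for HAT2, at 501 ± 71.3 in warm sfr3 and 457 ± 40.7 in warm wild type (log2 0.13). It stays open for the others, probe sets without a gene, which were lower in the warm too. These had -0.48 and -1.81 in the warm and -1.94 and -2.61 in the cold. Only the second was lower in the warm by at least 50% of the size. The first stood at 7.02 ± 1.82 in cold sfr3, not above background. Its -1.94 is a fitted value from such signals, so the 50% rule cannot decide for it. A difference between the genotypes in the cold stays as a hypothesis, found and tested on the same arrays, and the different wording of the tissue in the labels stays open as untested.

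The 69 plastid-encoded probe sets had a median cold response 0.575 higher (log2) in sfr3 than in wild type (adjusted p = 2.93e-05, and adjusted p = 0.862 with an estimated correlation), a median of 0.289 (adjusted p = 0.494) without cold sfr3 replicate 1, and 0.452 under quantile normalization and 0.264 with centring, so scaling stays open for much of the response. Against the wild-type warm mean, the median of these probe sets was 0.43 on cold sfr3 replicate 1 and -0.28 on cold sfr3 replicate 2. It was -0.18 and 0.05 on the cold wild-type arrays. The replicate 2 arrays of sfr3, at 0.0611 in the warm and -0.28 in the cold, did not show the higher response, which may thus rest on single arrays. In the warm the median in sfr3 was -0.38 against wild type. Scaling is argued against as the cause of the warm difference, since the value nearer to 0 of quantile normalization and centring was -0.32. A single array may account for it: the median of warm sfr3 replicate 2 alone was 0.0611 above the wild-type mean, while that of replicate 1, which had the highest actin 3'/5' ratio of the 8 arrays (4.69, with 1.38 to 2.84 on the others), was -0.84 with 65 of 69 lower. Members that move together stay open as well, as camera gave p = 0.194 with an estimated correlation.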

How the results depend on the processing

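Array weights, and gene list tests and agreement without cold sfr3 replicate 1, were chosen only after the data were seen. Of 4332 values of the 223 named results under other settings, 4132 kept their side of the threshold, 152 lost the call, 48 gained one (30 of these without cold sfr3 replicate 2) and 0 calls changed sign; 66 had no value under the stricter filter. Of the named calls, 27 of 35 for cold in wild type, 25 of 39 for cold in sfr3, 1 of 6 between genotypes in the cold and 0 of 2 for the interaction held in every setting. Of the list values, 106 kept their side, 11 lost the call and 3 gained one.

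With only the groups compared, the count for cold was 6551 in wild type and 1867 in sfr3, and that between genotypes was 1 in the warm and 4 in the cold. Array weights gave 6600, 2236, 1 and 10 for the same comparisons, with a weight of 0.230 for each of the cold sfr3 arrays and 2.12 for cold wild type. The spread of the cold sfr3 pair enters the common estimate in the 8-array fit, and under these settings the pair's own 2-group comparisons lost calls and the other 2 gained them; with weights the interaction had 7 calls and the average 7. Moderation without a trend gave 11 between genotypes in the cold, 0 for the interaction and 0 for the average. Centring on the median gave 0 for the interaction and 0 for the average, and quantile normalization 3 for the interaction. The correlation of the cold responses was 0.613 without a filter, which adds dim probe sets, against 0.882 with the stricter one. With an estimated correlation 0 of the gene list tests passed, against 6. The estimate was 0.0682 for the COR list, -0.281 for the starch list and -0.0232 for the flavonoid list. For the last 2, camera's unadjusted p in wild type still rose, from 0.00306 to 0.0403 and from 0.0273 to 0.0897. A positive correlation between their genes therefore does not account for that loss. The cause was not tested where none is given.

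Leaving out 1 array, with the lone array of its group assumed to vary like the others, gave 1500 to 6206 calls for cold in wild type, 2027 to 7981 for cold in sfr3, 0 to 1 between genotypes in the warm, 6 to 5372 in the cold, 0 to 3802 for the interaction and 0 to 3251 for the average. Without cold sfr3 replicate 1, 4227 probe sets were called with the same sign in both genotypes. Leaving out either cold sfr3 array takes the spread of that pair out of the estimate, but the counts between genotypes in the cold, for the interaction and for the average were 106, 16 and 22 without replicate 1 and 5372, 3802 and 3251 without replicate 2. In the second case cold sfr3 is represented by replicate 1 alone, the array that stands apart.

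Same-numbered arrays did not deviate together (r of replicate differences -0.0867 to 0.0525), so the replicate numbers share only a number. With the replicate block the counts were 3397, 4027, 0, 16, 4 and 7 in the order above, and 4 gene list tests passed. Lost with the block were the interaction call of HAT2 (adjusted p = 0.0685), SHN3 (0.0671) and AT5G33370 (0.0541) in wild type, AT2G05540 in the cold (0.0752), and the flavonoid list in wild type (0.0516) and the COR list in the warm (0.0546). What limits dim genes is signal over background: the background level was 35.4 on cold sfr3 replicate 1 and at most 11.3 elsewhere.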

Other observations

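The gene groups here were chosen after the data were seen, and the test of the leucine genes was fixed before its result but after another gene of the pathway was seen to fall. The 8 tested genes with autophagy (ATG) symbols were ATG3 and ATG8B to ATG8H, so all but ATG3 belong to a single gene family and do not stand for autophagy genes in general. Of these 8, 5 fell in the cold in wild type (6 adjusted over the list alone), with a median log2 value of -1.14. In sfr3 6 fell, with a median of -1.19. No scaling turned either direction. The log2 values in wild type and sfr3 were -3.70 and -5.01 for ATG8E, -2.69 and -2.88 for ATG8H and -1.34 and -1.55 for ATG8F. Without cold sfr3 replicate 1 those in sfr3 were -4.12, -1.80 and -1.32, all still called, and the group's median was -0.99. ATG8D had -0.16 and 0.32 and was called in neither genotype. As a group they stood lower than other genes by camera (adjusted p = 0.00564 in wild type and 0.0175 in sfr3; adjusted p = 0.788 and 0.762 with an estimated correlation). Of 10 serine carboxypeptidase-like (scpl) genes, 5 rose and 1, scpl50, fell in wild type, and 5 rose in sfr3, with medians of 0.73 and 0.95 that kept their sign under each scaling. Among them, scpl35 rose by 2.53 and 2.65 and scpl46 by 1.87 and 2.43. The group had an adjusted p of 0.0441 in wild type, 0.0676 without cold sfr3 replicate 1 and adjusted p = 0.788 with an estimated correlation, and it did not pass in sfr3 (adjusted p = 0.0524; 0.111 without cold sfr3 replicate 1, when the median was 0.53).

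MCCA, a subunit of an enzyme of leucine breakdown, fell in the cold in wild type (log2 -4.39, adjusted p = 6.66e-06) and in sfr3 (log2 -4.36, adjusted p = 5.56e-06). A hypothesis was that the other genes of this pathway fall too. IVD fell from 377 ± 84.2 to 45.2 ± 9.99 in wild type and from 453 ± 42.4 to 32.0 ± 31.8 in sfr3 (SD, n = 2), and MCCB fell in both (log2 -1.45 and -2.16). AT2G26800 fell in wild type (-0.77), and its value in sfr3 (-0.45) did not pass (-0.61, adjusted p = 0.0381, without cold sfr3 replicate 1). Camera gave p = 0.0102 in wild type and p = 0.00999 in sfr3 for the 3 genes, with medians of -1.45 and -2.16, and p = 0.0604 and 0.0599 with an estimated correlation. The data are in line with the hypothesis at the preset correlation, and 3 genes of a pathway may move together by chance.

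Sfr3 against wild type averaged over the temperatures compares 4 arrays with 4. Of the 18 ways to split the arrays within each temperature, the real one among them, 2 gave at least 7 calls: the real split with 7, and 1 other with 9. The split with 9 kept both cold sfr3 arrays against both cold wild-type arrays and exchanged only warm arrays. It still held the genotype difference in the cold, so it cannot stand for a grouping without one. These splits are too few for a share under 0.05.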
